A study of Mus musculus with 2 samples.

How the data were processed

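The series holds 2 single-cell RNA libraries of mouse aortic leukocytes gated on CD45, the surface antigen shared by white cells, resident macrophages included. The labels put 1 library in a group treated with ZnDPA@siIRF5, a preparation that carries a small interfering RNA against interferon regulatory factor 5 (IRF5), and 1 library in a control group. They are called here the library labelled treated and the library labelled control. No label gives the number of animals pooled, their genotype, diet, sex or age, or the contents of the control preparation.

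Per the labels' protocols, libraries were made with the 10x Genomics droplet kit that counts the 3′ end of polyadenylated transcripts. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 4.4.0 and the mouse build mm10 were used. Per the file headers, the matrices were written by Cell Ranger 7.2.0, and which of these versions made the counts is not settled by the sources used here. The deposited values are UMI counts (unique molecular identifiers, 1 for each captured transcript molecule) per gene and cell barcode, with no normalization. Whether intronic reads were counted is not given in the sources used here. The files list 32285 genes with Ensembl identifiers, of which 32158 were found in the GENCODE vM21 annotation of GRCm38, the assembly also known as mm10. Coordinates printed here come from that annotation.

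The library labelled treated held 13155 barcodes and 77856529 UMIs, with a median of 4449 UMIs per barcode. The library labelled control held 12516 barcodes and 88567528 UMIs, with a median of 4617. Barcodes with under 500 genes (511 and 352) or over 15% mitochondrial UMIs (359 and 301) were removed. Doublets, droplets with more than 1 cell, were called with Scrublet in scanpy 1.11.5 within each library, before those filters. It marked 593 barcodes (4.53%) in the library labelled treated and 533 (4.28%) in the library labelled control, against rates of 10.5% and 10.0% expected at these loadings, so part of the doublets will have stayed in. The kept cells were 11888 and 11523.

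Counts of kept cells were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes over both libraries, 30 principal components and 15 nearest neighbours entered Leiden clustering at resolution 1 (python-igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0). No batch integration was run, because library and group are the same. The 26 clusters were named only from 23 marker lists of cell classes, and macrophage-like cells were reclustered at resolution 0.5 into 10 sub-clusters, named from 5 lists of states. The lists were written before the data were examined. The scoring rules were set afterwards: only markers found in a single list were scored, a cluster with more markers of another class than of its own among its top 10 genes stayed unnamed, and a state name needed at least 1 of its own markers there. Clusters 3, 5 and 18 stayed unnamed and are described by number.

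For each class with at least 100 cells in each library, UMIs were summed per library and scaled to CPM by the library's total UMIs in that class. The log2 ratio is that of the library labelled treated over the library labelled control. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95%. They cover counting error only. With 1 library per group there is no test, no p-value and no count of changed genes, and differences between the mice, dissections and libraries cannot be separated from the treatment. A count of 0 was set to a floor of 3 UMIs, and the ratio is then a bound. Under the alternatives, a gene with 0 UMIs in a library got no ratio where the bound did not exclude 0.

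Genes were named by a rule of size fixed before the data were examined: the 12 highest and 12 lowest log2 ratios in macrophage-like cells and the 5 highest and 5 lowest in each other class. A gene entered with at least 50 UMIs and 20 CPM in one of the libraries. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, predicted, immunoglobulin segment and T cell receptor segment genes were left out. From each gene list up to 4 members with the largest absolute ratio were named, with any member whose level itself was the point. Some genes that this rule names are not reported here. The 26 gene lists and a check of sex-linked genes were also fixed beforehand. For each list the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. The interval of a median comes from 200 Poisson redraws of the counts. In classes other than macrophage-like cells, only lists of at least 8 measured members with a median of at least 0.3 in size and outside the central 95% of random lists are given, a limit chosen after the data were seen. Of the genes in the marker and gene lists, 4 (Aldoa, Mx1, Mx2, Sepp1) were not found under those symbols. The sex-linked check gave a median of -0.17 over 4 measured genes in macrophage-like cells, at percentile 1.86 of random lists (central 95% -0.16 to 0.27). It pools Xist with genes of the Y chromosome, so this median alone cannot show whether the libraries differ in sex. In macrophage-like cells none of the 4 genes was at least 1.5-fold higher or lower, which argues against a male library set against a female one. In neutrophil-like and in NK cell-like cells 1 of the 4 was at least 1.5-fold lower. Pools that mix the sexes stay open.

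Shares of cells with an Irf5 UMI are given as measured and after each cell was thinned to 2000 UMIs. The summing, interval and list steps were tested on simulated data drawn from the macrophage-like sums: of 200 genes with a simulated 2-fold difference among 5716, 100% came out in the right direction within 0.5 on the log2 scale, and 95.0% of the intervals held the simulated ratio. Of simulated lists without a difference, 95% fell inside the central range of random lists. The draws were Poisson counts of whole sums, the assumption behind the intervals, so this checks the calculation alone. It cannot show the wider spread of genes with many UMIs in 1 cell.

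The alternatives fixed beforehand were trimmed mean of M-values scaling (edgeR 4.0.16 in R 4.3.3, used for its scaling factor alone), median of ratios scaling, totals without mitochondrial and ribosomal protein genes, equal weights for cells, the same weights for each cluster in both libraries, cells with at most 1 UMI of T cell, B cell and neutrophil markers, thinning to the same median depth, other limits on genes and mitochondrial UMIs, doublet calls kept, other clustering resolutions, and genes centred within each library before clustering. Some alternatives were added after the data were seen: a total without immunoglobulin genes, macrophage-like cells without some sub-clusters or together with monocyte-like cells, shares without the germinal centre, plasma cell and granulocyte precursor clusters, and each named gene without the cell holding most of its UMIs. The minimum of 100 cells per library for an alternative was applied after a first run with a minimum of 20. Figures were drawn with matplotlib 3.10.9.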

Results

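Aortic leukocytes were profiled by droplet single-cell RNA sequencing in 2 libraries, 1 labelled as treated with ZnDPA@siIRF5 and 1 labelled as control, to ask what an siRNA against IRF5 does to macrophages of the aortic lesion. After filtering, 11888 cells with a median of 4556 UMIs remained in the library labelled treated and 11523 cells with a median of 4630 UMIs in the library labelled control. There were no replicates, so every difference given here is between 2 libraries, and every interval covers counting error only. Immunoglobulin genes took 5.40% of all UMIs in the library labelled treated and 15.3% in the library labelled control.

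Irf5, the target of the siRNA, was in no class lower beyond counting error in the library labelled treated. Irf5 encodes a transcription factor that acts below Toll-like receptors and drives inflammatory cytokine genes. Macrophage-like cells held 124 CPM of Irf5 (95% interval 119 to 130) in the library labelled treated and 112 CPM (106 to 119) in the library labelled control, a log2 ratio of 0.15 (0.04 to 0.25). The level was also higher in monocyte-like cells (157 against 125 CPM, log2 ratio 0.33, 0.19 to 0.46) and in neutrophil-like cells (51.6 against 32.9 CPM, log2 ratio 0.65, 0.39 to 0.91). In cDC1-like cells, the cross-presenting dendritic cells and the class with most Irf5, the values were 233 and 236 CPM, and in migratory DC-like cells 143 and 141 CPM, differences within counting error. The lowest ratio was that of plasmacytoid dendritic (pDC-like) cells, 44.7 against 67.8 CPM from 40 and 37 UMIs (log2 ratio -0.60, -1.28 to 0.08), and the intervals also held 0 in ILC2-like cells (-0.19), which resemble type 2 innate lymphoid cells, and in NK cell-like cells (-0.08).

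An Irf5 UMI was found in 48.4% (46.2 to 50.5) of macrophage-like cells of the library labelled treated and in 45.3% (42.8 to 47.8) of those of the library labelled control, at median depths of 5971 and 5989 UMIs. Thinned to 2000 UMIs per cell, the shares were 21.5% (19.7 to 23.4) and 19.9% (17.9 to 22.1), with 224 and 130 shallower cells left out. T cell-like cells, which should hold little Irf5, gave 2.91% and 2.38% after the same thinning and 6.31% and 4.70% before it, at median depths of 4584 and 3947 UMIs. The gene (ENSMUSG00000029771) lies on the plus strand of chromosome 6 from 29526625 to 29541871 in GRCm38. The counts come from the 3′ end of transcripts, and the site the siRNA targets is not given in the sources used here. Since Irf5 was not lower in the library labelled treated, the labels could not be checked by the target. The directions below are those of the libraries as labelled. The log2 ratio in macrophage-like cells stayed above 0 in the alternatives run but ranged from 0.07, in cells with at most 1 UMI of T cell, B cell and neutrophil markers, to 0.27 with monocyte-like cells included.

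**Figure D1:**
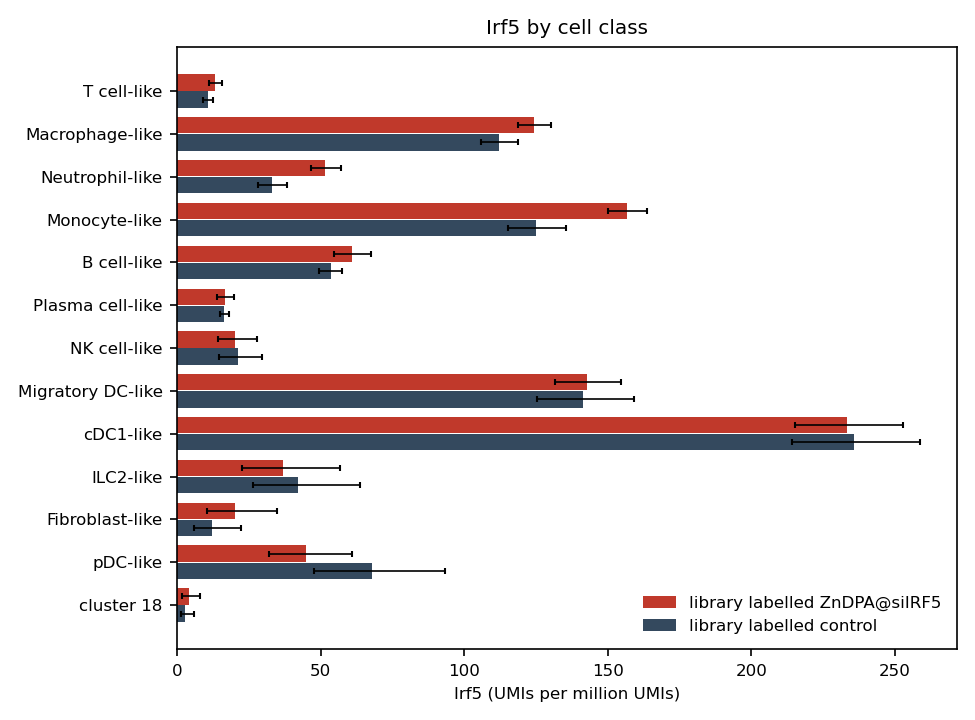
Irf5 in CPM (horizontal axis) for each cell class (vertical axis), with red bars for the library labelled ZnDPA@siIRF5, dark bars for the library labelled control and whiskers for exact 95% Poisson intervals, which cover counting error only. Macrophage-like cells stand at 124 and 112 CPM, and in no class is the red interval wholly below the dark one.

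Myeloid cells made up more, and lymphoid cells less, of the library labelled treated. Monocyte-like cells were 18.5% (17.8 to 19.2) of its cells against 6.53% (6.08 to 6.99) in the library labelled control, a 2.83-fold higher share. Macrophage-like cells were 17.96% (17.3 to 18.7) against 13.7% (13.1 to 14.3), and neutrophil-like cells 19.98% (19.3 to 20.7) against 11.4% (10.8 to 11.98). T cell-like cells were 15.3% (14.7 to 16.0) against 25.7% (24.9 to 26.5), B cell-like cells 7.98% (7.50 to 8.48) against 16.2% (15.6 to 16.9), and antibody-secreting plasma cell-like cells 3.36% (3.05 to 3.70) against 10.7% (10.1 to 11.3).

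Within these classes, single clusters differed most. Cluster 25, B cell-like cells with the germinal centre gene Rgs13 among their leading genes, held 0.656% of cells in the library labelled treated and 3.15% in the library labelled control. Cluster 21, plasma cell-like cells led by the cell cycle genes Rrm2 and Ube2c, held 0.168% and 1.61%. Monocyte-like cells fell into cluster 4, led by Vcan, F10 and Chil3 (14.1% against 4.74%), and cluster 8, led by the patrolling monocyte markers Ace and Treml4 (4.43% against 1.79%). Neutrophil-like cells lay mostly in cluster 9, and cluster 22, with the granule genes Elane, Prtn3 and Mpo of granulocyte precursors, held 0.984% and 0.772%.

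Among the smaller classes, migratory DC-like cells, led by Fscn1, Il4i1 and the conventional dendritic cell gene Cd209a, were 3.84% (3.50 to 4.20) against 1.96% (1.72 to 2.23), and cDC1-like cells 1.70% (1.47 to 1.95) against 1.21% (1.02 to 1.43). The intervals overlapped for NK cell-like cells (3.24% against 3.50%), for ILC2-like cells (1.05% against 1.21%) and for fibroblast-like cells (0.824% against 1.01%). Unnamed cluster 18, led by Cd8a, Cd8b1, Gzmk and Nkg7, held 4.11% (3.76 to 4.49) and 5.76% (5.34 to 6.20), and unnamed cluster 3, led by Saa3 and Prg4, held 0.151% and 0.113%. The CD45 gate and tissue cleaning shape such shares, and a larger share of one class lowers the others. At clustering resolution 0.5 the monocyte-like shares were 4.11% and 1.72%, and with a minimum of 1000 genes the neutrophil-like shares were 9.48% and 4.85%.

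**Figure D2:**
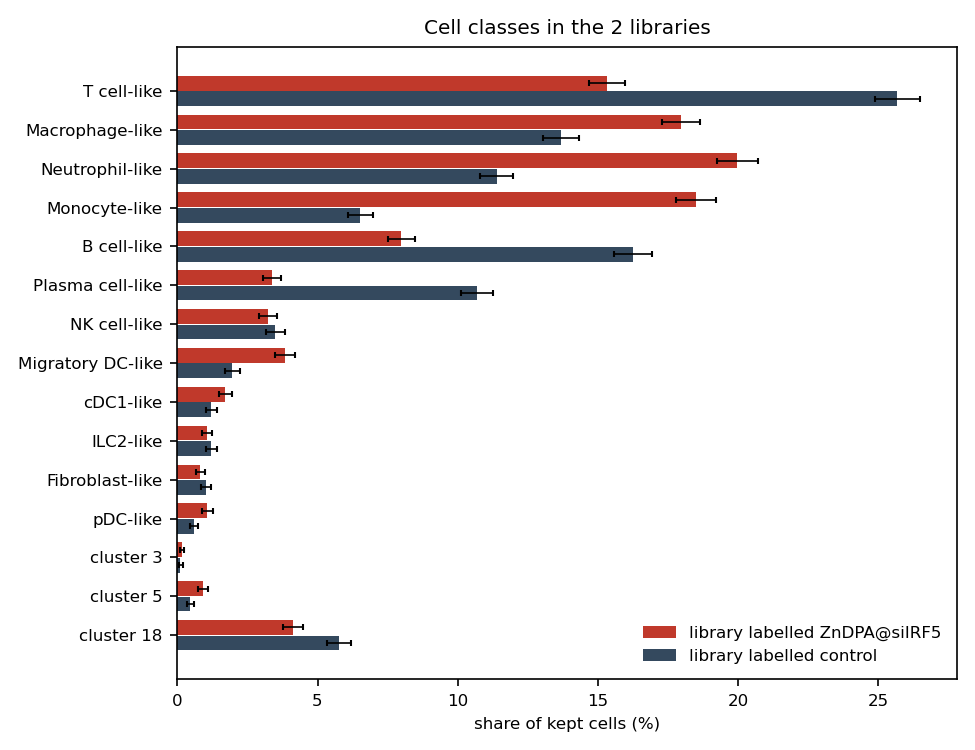
Share of kept cells in percent (horizontal axis) for each cell class and unnamed cluster (vertical axis), with red bars for the library labelled ZnDPA@siIRF5, dark bars for the library labelled control and whiskers for exact 95% Clopper-Pearson intervals, which cover counting error only. Monocyte-like cells reach 18.5% against 6.53%, and T cell-like cells 15.3% against 25.7%.

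In macrophage-like cells, Dbp, Nr1d1, Cxcl9 and Thbs1 had the highest ratios of the genes that met the size rule. Dbp, a transcription factor under direct control of the circadian clock, was 3.91-fold higher in the library labelled treated (21.8 against 5.58 CPM, log2 ratio 1.97, 1.56 to 2.39), and the clock repressors Nr1d1 and Nr1d2 were higher by log2 ratios of 1.43 (1.14 to 1.74) and 0.99 (0.80 to 1.18). The interferon-inducible chemokine Cxcl9, which draws CXCR3-bearing lymphocytes, had 20.2 against 7.76 CPM (log2 ratio 1.38, 1.02 to 1.75), and the guanylate-binding protein Gbp2 66.0 against 31.0 CPM (1.09, 0.91 to 1.27). Thbs1, a secreted glycoprotein that can bridge dying cells to phagocytes, had 204 against 78.7 CPM (1.37, 1.26 to 1.48). At the bottom stood genes of B cells and plasma cells, led by the B cell transcription factor Ebf1 (24.97 against 99.8 CPM, log2 ratio -2.00, -2.18 to -1.82).

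The other genes among the 12 highest were Ifit2 (1.35), Plxnd1 (1.30), the acute phase gene Saa3 (1.08), Calhm6 (1.07), the immunity-related GTPase Iigp1 (1.01) and the guanylate-binding protein Gbp5 (0.99). The other 11 lowest were the B cell receptor component Cd79a (-1.61), the plasma cell genes Mzb1 (-1.53) and Jchain (-1.41), Ly6d (-1.38), Jaml (-1.29), Fhit (-1.16), H2-DMb2 (-1.08), Rnf180 (-1.03), the core clock activator Arntl (-1.03), Serpinb2 (-1.01) and the B cell chemoattractant Cxcl13 (-0.99). The rule picks the ends of the range, so these genes lay beyond most others by selection. Of the 5672 genes that met the abundance rule, the central 95% had log2 ratios between -0.44 and 0.48. The immunoglobulin light chain Igkc, left out of the naming rule, had 596 and 2393 CPM in macrophage-like cells, so RNA of antibody-secreting cells in these droplets was lower in the library labelled treated by the same measure. Ebf1 UMIs lay in 56 and 134 cells, and sub-clusters led by genes of other lineages held 5.90% and 9.33% of macrophage-like cells. With the macrophage sub-clusters given the same weights in both libraries the ratio was -0.35 for Ebf1, -0.24 for Cd79a, -0.067 for Ly6d and -0.40 for H2-DMb2, and with monocyte-like cells included it was -0.69 for Mzb1, -0.094 for Jchain, -0.18 for Jaml and -0.47 for Serpinb2. Thbs1, also among the leading genes of monocyte-like cluster 4, was at 0.79 at clustering resolution 2. Saa3 had 36.8% and 52.2% of its UMIs in a single cell of each library.

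**Figure D3:**
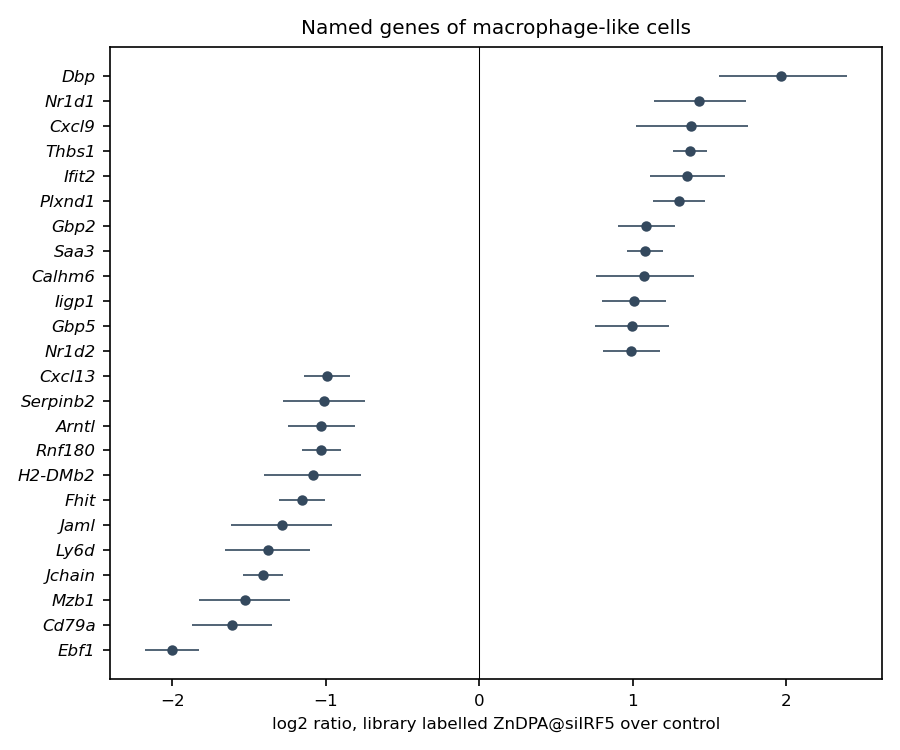
Log2 ratio of CPM in macrophage-like cells, library labelled ZnDPA@siIRF5 over library labelled control (horizontal axis), for the 12 highest and 12 lowest genes by the size rule (vertical axis), with exact 95% intervals that cover counting error only. Dbp lies at 1.97 and Ebf1 at -2.00.

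Genes that respond to interferon gamma, the macrophage-activating cytokine of T and NK cells, were higher as a group in macrophage-like cells of the library labelled treated. All 14 measured members of that list had ratios above 0, 9 of them at least 1.5-fold, and the median was 0.88 (0.70 to 0.95), against -0.08 to 0.19 for the central 95% of random lists. Besides Cxcl9, Gbp2, Iigp1 and Gbp5, the peptide transporter Tap1 was at 0.96 (76.4 against 39.2 CPM), while Socs1, a feedback inhibitor of cytokine signalling, was level (25.2 against 25.1 CPM). The type I interferon response list had a median of 0.35 (0.26 to 0.45), with 20 of 22 members above 0, among them the nucleic acid sensor Zbp1 (0.81) and Ifit3 (0.79), while Isg15 (0.04) and Cxcl10 (0.10) were close to level. In the IRF family the median was 0.22 over 8 members: Irf1 was at 0.96 (127 against 65.6 CPM), Irf7 at 0.71, Irf8 at 0.29 and Irf4 at -0.42.

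At most 1 UMI of T cell, B cell and neutrophil markers was found in 836 of 2135 and 725 of 1576 macrophage-like cells. In these cells the interferon gamma list had a median of 0.58 and the type I list 0.16. Gbp2 was at 0.51, Calhm6 at 0.62, Saa3 at -1.49 and H2-DMb2 at -0.097. Few UMIs were left there for Cxcl9 (35 and 39, log2 ratio -0.17, -0.87 to 0.52) and Cd79a (9 and 5, 0.83, -0.90 to 2.76).

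Efferocytosis, the uptake of dying cells, is named in the title of the series, and the list median of its genes was near 0 in macrophage-like cells as a whole. Of 22 measured members of the list for recognition and engulfment of apoptotic cells, 11 were above 0 and 11 below, with a median of -0.01 (-0.09 to 0.03) inside the range of random lists (-0.08 to 0.10). Within sub-clusters the median was below 0 in 9 of 10, from -0.15 to -0.05, among them all 7 with at least 50 cells in each library, and 0.33 in a sub-cluster of 18 and 52 cells. These medians were not set against random lists and have no interval, and the sub-clusters are parts of the same 2 libraries. The receptor tyrosine kinase Mertk, a main receptor for dying cells, had 98.7 against 87.5 CPM (log2 ratio 0.17, 0.05 to 0.29), its relative Axl 95.1 against 94.2 CPM (0.01) and their bridging ligand Gas6 322 against 287 CPM (0.17). Thbs1 (1.37) and the lipid receptor Cd300lf (0.51) were higher, and the phosphatidylserine receptor Timd4 (-0.60) and the bridging protein Mfge8 (-0.44) lower. The list for digestion of cargo in lysosomes had a median of 0.13, with 13 of 22 above 0, and held Ucp2 (-0.53), a mitochondrial carrier, and the proton pump subunit Atp6v0d2 (0.31). That median was -0.0041 in cells with at most 1 foreign marker UMI. With monocyte-like cells included the engulfment median was -0.24 and the lysosome median -0.036.

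The cytokine genes Il1b, Tnf and Il6 were close to level. Il1b, the gene of interleukin-1 beta, had 1393 against 1466 CPM (log2 ratio -0.07, -0.10 to -0.04), Tnf 672 against 702 CPM (-0.06, -0.11 to -0.02) and Il6 95.3 against 83.9 CPM (0.18, 0.06 to 0.31). The list of inflammatory cytokines and mediators had a median of -0.10 (-0.18 to -0.06), at percentile 2.44 of random lists and so just below their central 95% (-0.10 to 0.10), with 7 members above 0 and 12 below. The chemokines Ccl3 (-0.42), Ccl7 (-0.39) and Cxcl2 (-0.34) were lower and Cxcl3 (0.65) higher. Nos2, the inducible nitric oxide synthase, had 28 UMIs against 1 (log2 ratio 4.36, 1.76 to 9.71). The list median ranged from -0.27, at clustering resolution 0.5, to -0.01, at resolution 2. Genes of alternative activation had a median of -0.08, with Cd163, a scavenger receptor of tissue macrophages, at -0.74, Chil3 at 0.97, Nr4a1 at 0.55 and Cd200r1 at 0.34, and were at -0.22 with monocyte-like cells included. Signalling genes upstream of IRF5 had a median of 0.09, with the endolysosomal transporter Slc15a4 at 0.50, Tlr4 at 0.22, Tlr7 at -0.19 and Tlr2 at -0.24.

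Genes of resident macrophages were mostly lower and genes of recruited monocytes mostly higher. The resident list had a median of -0.11 with 14 of 19 members below 0, among them Cd163, the hyaluronan receptor Lyve1 (-0.64) and Timd4, while Ccl24 was at 0.85, and the median ranged from -0.49, with monocyte-like cells included, to -0.066, with doublet calls kept. The list for monocyte recruitment and adhesion had a median of 0.19 with 10 of 15 above 0, among them the monocyte markers Ly6c2 (0.70) and Plac8 (0.64), while the chemokine receptor Ccr1 was at -0.52 and the adhesion gene Vcam1 at -0.47. Antigen presentation by MHC class II had a median of 0.17 with 10 of 12 above 0, including the class II transactivator Ciita (0.45) and H2-Ab1 (0.26), and was at -0.029 with monocyte-like cells included. Proliferation genes had a median of -0.30 with 14 of 18 below 0, including Birc5 (-0.65) and Stmn1 (-0.41), and were at 0.042 with sub-clusters given the same weights in both libraries.

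Lipid handling was mixed, with a median of 0.07 and 17 of 25 above 0. The cholesterol exporter Abcg1 was at 0.76 (145 against 85.5 CPM) and the lipoprotein lipase gene Lpl at 0.67, while the scavenger receptor Cd36 was at -0.31. The foam cell list had a median of 0.11, with Trem2, the lipid-sensing receptor of foamy macrophages, at 227 against 230 CPM, Spp1 at -0.32 and Mmp12 at -0.47, and was at -0.092 in cells with at most 1 foreign marker UMI. Matrix remodelling genes had a median of 0.03, with the collagen-degrading protease Ctsk at 0.88, Mmp9 at 0.83 and fibronectin, Fn1, at 0.70 but Mmp13 at -0.86. A list that joins signals that restrain phagocytosis, checkpoint genes such as Cd274 and Pdcd1, and Calr, not itself a restraining signal, had a median of 0.05. In it Sirpa, the receptor for the signal CD47, was at 0.52 and Cd47 at 0.13. Oxidative phosphorylation had a median of 0.16 (16 of 18 above 0), glycolysis 0.09, apoptosis 0.12 and the immediate early and heat shock list 0.07, in which Hspa1b was at 0.77. In cells with at most 1 foreign marker UMI the medians were 0.023 for oxidative phosphorylation, 0.053 for apoptosis, -0.016 for glycolysis and -0.063 for matrix remodelling, and with monocyte-like cells included the immediate early list was at -0.064. The lipid median reached 0.20 with genes centred within each library.

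Lists of T cell genes, which in macrophage-like cells may report other cells or free RNA, a source not tested here, had medians below 0. They were -0.40 (-0.63 to -0.01) for naive and central memory T cells, -0.17 (-0.45 to -0.11) for T cell activation and -0.45 (-0.74 to -0.24) for type 17 cells, and the intervals held 0 for regulatory T cells (-0.28, -0.51 to 0.08) and type 2 cells (-0.30, -0.51 to 0.03). The cytotoxic list was at 0.03 with 12 members measured, and at 0.57 in cells with at most 1 foreign marker UMI. Without the sub-clusters led by other lineages and the sub-cluster of low UMIs, the naive T cell median was 0.031. The type 17 median was 0.88 with doublet calls kept, the type 2 median 0.054 in cells with at most 1 foreign marker UMI, and with monocyte-like cells included T cell activation was at 0.016 and regulatory T cells at 0.0012.

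**Figure D4:**
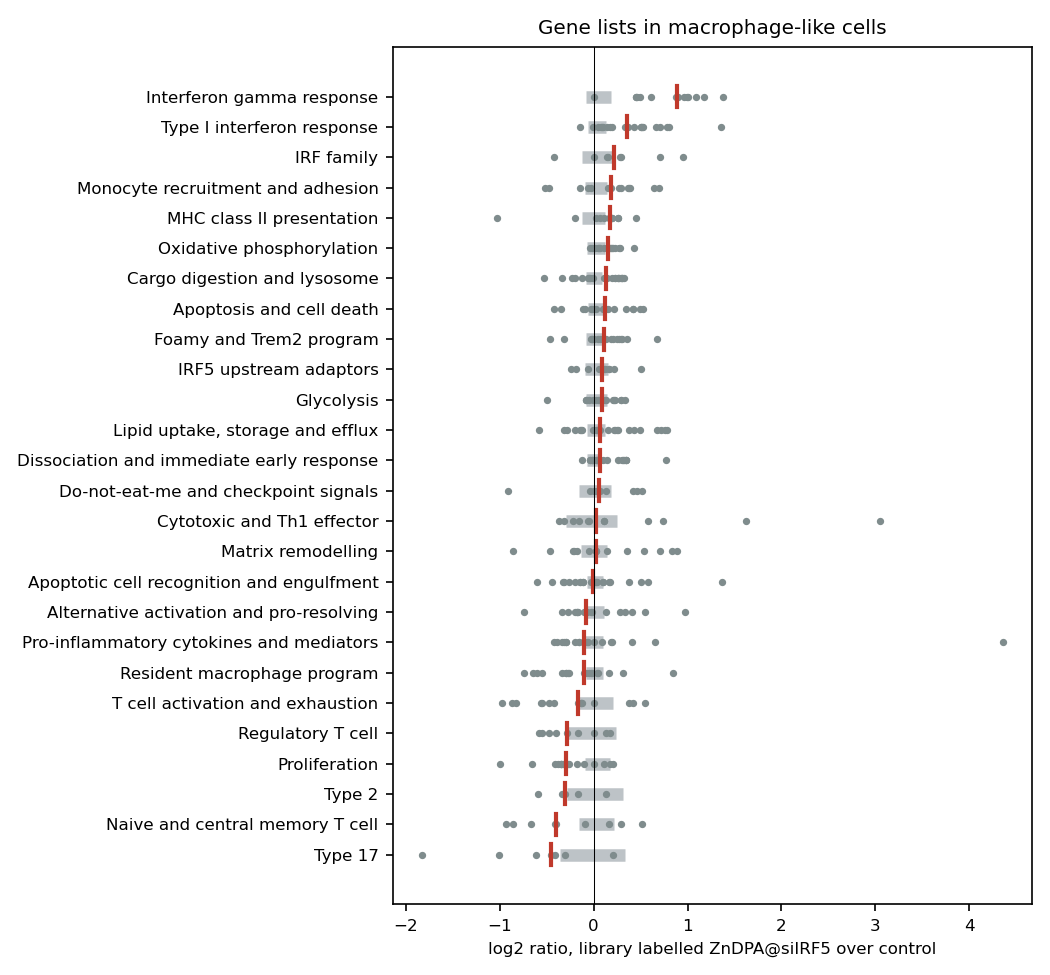
Log2 ratio of CPM in macrophage-like cells, library labelled ZnDPA@siIRF5 over library labelled control (horizontal axis), for each gene list (vertical axis), with grey points for members with at least 20 UMIs, red ticks for list medians and grey bands for the central 95% of medians of 10000 matched random lists. The interferon gamma list lies at 0.88 and the engulfment list at -0.01, and the point farthest right is Nos2 at 4.36, with 28 UMIs against 1.

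Macrophage states were described by reclustering the macrophage-like cells. Cells in an inflammatory state, led by the chemokine genes Ccl4 and Ccl3, made up 25.5% (23.6 to 27.4) of macrophage-like cells in the library labelled treated and 23.1% (21.0 to 25.3) in the library labelled control. Resident-state cells, with Lyve1 and Cd163 among their leading genes, made up 21.7% (20 to 23.5) and 29.2% (27.0 to 31.5), foamy Trem2-state cells, led by Spp1 and Ctsk, 9.98% (8.74 to 11.3) and 9.20% (7.82 to 10.7), and proliferating cells 1.55% (1.07 to 2.16) and 2.09% (1.45 to 2.93). A sub-cluster of low UMI count held 9.46% and 4.70%. State shares depended on the reclustering: at resolution 1 the inflammatory shares were 6.09% and 10.5%, and at resolution 0.3 the foamy shares were 18.3% and 20.9%. Genes that define the states differ between the libraries too, so clusters and libraries are not independent.

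Other leukocytes of the same libraries shared part of these differences. In monocyte-like cells the interferon gamma list was higher (median 0.47, 14 of 14 measured members above 0), with Cxcl9 at 88.8 against 35.6 CPM and Gbp5 at 87.7 against 41.7 CPM, and in migratory DC-like cells it was at 0.42. The monocyte-like median ranged from 0.28 at clustering resolution 2 to 1.16 at resolution 0.5. In lymphocytes the type I interferon genes went the other way: the list median was -0.47 in T cell-like, -0.57 in B cell-like and -0.45 in NK cell-like cells, with -0.24, -0.35 and -0.23 as the values closest to 0 over the alternatives, and Ifit1, a translation inhibitor induced by interferon, had 9.30 against 37.5 CPM in T cell-like cells. Ifng, the interferon gamma gene itself, had 76.8 against 27.4 CPM in T cell-like cells (log2 ratio 1.49, 1.31 to 1.67), but 57.1% of the UMIs in the library labelled treated came from 1 cell. Without the cell with most Ifng UMIs in each library the values were 33.0 (29.5 to 36.8) and 22.2 (19.8 to 24.8) CPM, a log2 ratio of 0.57. An Ifng UMI was found in 67 of 1821 and 138 of 2959 T cell-like cells, a smaller share in the library labelled treated, for which no interval was computed. In NK cell-like cells Ifng had 99.4 against 87.7 CPM and in cluster 18 it had 52.7 against 59.7 CPM, both within counting error.

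T cell-like cells also had higher Cdh18, a cadherin gene (32.7 against 2.11 CPM, in 209 and 24 cells), Hist1h2ap (log2 ratio 1.05), S100a4 (0.96) and Gstp1 (0.93), and lower Gzma, the gene of granzyme A (47.8 against 169 CPM), Slpi (-1.79), Ifit3 (-1.40) and Dgki (-1.33). Gzma was at 0.33 at clustering resolution 0.5 and Ifit3 at -0.75 with doublet calls kept. B cell-like cells had lower levels of the germinal centre genes Gcsam (9.09 against 40.9 CPM), Mybl1 (-2.17), S1pr2 (-2.13) and Nuggc (-2.13) and of the mitotic cyclin Ccnb1 (15.8 against 74.6 CPM), and 16 of 18 proliferation genes were at least 1.5-fold lower (list median -1.25). With the B cell-like clusters given the same weights in both libraries that median was -0.29, and the 5 genes lay between -1.20 and -1.02. Cdh18 (20.03 against 0.382 CPM), Ccl22, Ifitm1, Ly6k and Ifitm2 were highest, Ccl22 with UMIs in 10 and 7 cells, and Ifitm1 was at 0.89 with doublet calls kept. In plasma cell-like cells all 18 proliferation genes were lower (median -1.21), among them Ccnb1, Ccnb2, Pclaf and Ccna2, as was Cxcr3 (6.28 against 24.7 CPM). That median was 0.037 with clusters given the same weights in both libraries and 0.43 at clustering resolution 0.5, where Pclaf was at 1.29 and the intervals of Ccnb1 and Ccna2 held 0. Chil3, the heat shock gene Hspa1b, Ifitm1, Slc7a11 and Il1b (170 against 22.0 CPM) had the highest ratios there, and the immediate early and heat shock list was at 0.55 (19 of 22 above 0). Chil3 and Il1b may report other cells or free RNA there, a source not tested here, and S100a8 had 352 against 107 CPM. With doublet calls kept Il1b was at 1.36, against 2.95 without, Chil3 at 2.39, Ifitm1 at 1.23 and Slc7a11 at 1.30.

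In neutrophil-like cells 15 of 19 inflammatory mediators were above 0 (median 0.50), among them Il6 (54.4 against 12.2 CPM, in 56 and 17 cells) and the neutrophil chemoattractant Cxcl3 (261 against 80.6 CPM). That median was 0.11 with clusters given the same weights in both libraries, and Il6 was at 0.93 with genes centred within each library, against 2.16. The immediate early and heat shock list was at 0.33, with 16 of 22 above 0, and at 0.14 with doublet calls kept. Prg2 and Cxcl9 had no UMI in the library labelled control, but 98.8% and 91.6% of their UMIs in the other library came from 1 cell, and 52.2% of those of Ikzf2. Elane, of granulocyte precursors (346 against 1259 CPM), Gzma, Lipg, Mzb1 and Jchain were lowest, and with a minimum of 1000 genes per cell Jchain was at 1.27 and Mzb1 at 0.33. With doublet calls kept Gzma was at -0.14, against -4.35, Elane at -3.81, against -1.86, and Ikzf2 at -0.85, and Prg2 had 3 UMIs against 0, too few for a ratio. In monocyte-like cells Cfd (log2 ratio 5.44, in 15 and 2 cells), the granule genes Camp (3.81) and Ngp (2.77), Ccl24 (2.76) and Retnla (2.16) were highest, of which Camp, Ngp and Cfd had ratios below 0 in most alternatives that redrew the clusters, in part within counting error, and Ccl24 was at 0.69 (-0.34 to 1.86) at clustering resolution 2 and had 2 UMIs against 0 at resolution 0.5. Il22ra2, Sox5, Negr1, the apolipoprotein gene Apoc2 (44.6 against 157 CPM) and the lymph node homing receptor Ccr7 (21.7 against 61.6 CPM) were lowest, Il22ra2 with 93.9% of the UMIs in the library labelled control in 1 cell. In cells with at most 1 foreign marker UMI Sox5 was at -0.61 and Negr1 at -0.64, and with genes centred within each library Apoc2 was at -1.07 and Ccr7 at -0.71.

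The remaining classes were small. NK cell-like cells had higher MHC class II genes (median 1.06, and 0.22 with cells weighted equally) and higher Il1b (119 against 26.1 CPM, 43.5% of it in 1 cell), Cd14, Clec4e, Serpinb9b and Pdpn, and lower Slpi (23.3 against 103 CPM), Ramp3, Magi1, Jchain and Themis. MHC class II, Il1b, Cd14 and Clec4e may report other cells or free RNA in these droplets, a source not tested here. The neutrophil marker S100a8 had 114 against 58.5 CPM in NK cell-like cells. With doublet calls kept Il1b was at 0.46 there, Cd14 at 0.99 and Clec4e at 0.31, against over 2 without, Pdpn (63 UMIs against 2) had 0 and 2 UMIs with a minimum of 1000 genes, and Themis was at -0.47 at clustering resolution 2. Migratory DC-like cells had higher Slamf8 (35.3 against 11.1 CPM, in 84 and 18 cells, log2 ratio 1.67 but 0.39 at clustering resolution 0.5) and lower H2-M2 (9.71 against 55.4 CPM), and in the library labelled control 80.0% of Tnfsf11 and 83.3% of Prtn3 came from 1 cell. In cDC1-like cells Thbs1 had 40.4 against 2.65 CPM, and the interleukin-12 subunit gene Il12b 33.2 against 134 CPM. ILC2-like cells had higher Cd3g (303 against 105 CPM) and lower H2-Eb1 (49.5 against 485 CPM), with 58.3% of the H2-Eb1 UMIs of the library labelled control in 1 cell and a log2 ratio of -3.29, or -1.10 with doublet calls kept. Cluster 18 had higher Cdh18 (at least 30.3-fold, 75 UMIs against 0), Ank3 and Coch and lower Ifitm1 (41.4 against 249 CPM) and Slpi (24.6 against 134 CPM). Jchain was among the lowest genes in neutrophil-like, NK cell-like, macrophage-like and cluster 18 cells alike.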

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

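The background and label exchange tests of Irf5, the Ifng test, the opposite-phase count and the dissociation tests were chosen after their results were seen, and the clock gene list was drawn up after the macrophage-like values were seen. The type I interferon list was higher in macrophage-like cells of the library labelled treated (0.35) but lower in T cell-like (-0.47, and -0.24 with doublet calls kept), B cell-like (-0.57) and NK cell-like cells (-0.45). The interferon gamma list was at -0.39 in plasma cell-like cells (-0.25 with clusters given the same weights in both libraries) against 0.88 in macrophage-like cells. The naive T cell list was at 0.48 in B cell-like cells against -0.40 in macrophage-like cells, but at 0.040 in B cell-like cells with clusters given the same weights in both libraries, and at 0.031 in macrophage-like cells without the sub-clusters led by other lineages and of low UMIs. None of these differences between classes was tested. Plasmacytoid dendritic (pDC-like) cells, left out of the lists and named genes for under 100 cells in a library, were 1.07% (0.891 to 1.27) of the library labelled treated and 0.581% (0.451 to 0.738) of the library labelled control. Unnamed cluster 5, led by the mast cell genes Mcpt4, Cma1 and Cpa3, was 0.917% (0.753 to 1.11) and 0.451% (0.337 to 0.591). Apart from the Irf5 level of pDC-like cells, both lie outside the sums compared in the report.

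Irf5 was not lower in macrophage-like cells of the library labelled treated. With the whole T cell-like level taken off the library labelled treated alone, as the most that background allows, the ratio was still 0.99, which argues against free RNA hiding a lower level. Over 7 sub-clusters with at least 50 cells in each library the median log2 ratio was 0.11, which argues against a shift between states hiding it. The ratio was below 0, with intervals that held 0, in a sub-cluster with Hspa1b among its leading genes (-0.21, -0.54 to 0.12). The same held in a sub-cluster led by T cell genes (-0.38, -0.85 to 0.09), and the others were above 0. An exchange of the 2 labels stays open: among the classes whose Irf5 interval excluded 0, it lay at percentile 71.1 of the measured genes in macrophage-like, 92.6 in monocyte-like and 97.1 in neutrophil-like cells, not high enough to decide. A lower protein level, or an effect gone or not yet present when cells were taken, might also leave such counts, and was not tested.

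The interferon gamma list was higher in macrophage-like cells of the library labelled treated, with a median of 0.88. The lowest median over the scalings and thinning was 0.77, and over 7 sub-clusters the median was 0.73 (0.28 to 0.94). Both values argue against scaling, depth or the mix of states as the whole cause, though the list was much less raised in some sub-clusters. Ifng was higher in T cell-like cells (log2 ratio 1.49) and still higher without the leading cell of each library (0.57). The share of T cell-like cells with an Ifng UMI was smaller in the library labelled treated (67 of 1821 against 138 of 2959). No interval was computed for this share, so it decides nothing. The intervals of Ifng CPM overlapped in NK cell-like and cluster 18 cells, so more Ifng message in lymphocytes stays open. Doublets may account for part of it and stay open. The median was 0.58 in cells with at most 1 UMI of T cell, B cell and neutrophil markers (836 of 2135 and 725 of 1576). That limit also removes cells for free RNA of these markers, such as S100a8 (236 and 141 CPM), so it cannot single out doublets. The treatment and any other difference between the mice cannot be separated here, so no biological cause was tested.

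Clock genes differed between the libraries: in macrophage-like cells the median log2 ratio was 0.98 over 8 output genes such as Dbp and Nr1d1 and -0.11 over 3 genes of the opposite phase, while Arntl was at -1.03. The difference between these medians, which was 1.08 in macrophage-like cells, was above 0.2 in 9 of 10 classes, all but B cell-like cells (0.021), and it was -0.25 in unnamed cluster 18, with only 2 output genes measured in cDC1-like and ILC2-like cells. Tissue taken at another time of day may be the cause. Its prediction set beforehand, a difference above 0.2 in at least 8 of 10 classes, was met. But the clock gene list was drawn up after the macrophage-like values were seen, and all classes come from the same 2 libraries. The classes are therefore not independent support. Time of day is held open by a count chosen afterwards: the opposite-phase median was below 0 in only 5 of the 10 classes. In T cell-like (0.012), plasma cell-like (0.011), migratory DC-like (0.0081) and cDC1-like cells (0.025) the difference rests on output genes. The immediate early and heat shock list, at 0.065 in macrophage-like cells, argues against dissociation stress there, but stress stays open elsewhere, as the list reached at least 0.25 of the clock difference in 3 of the other 8 classes above 0.2, among them plasma cell-like (0.55 against 0.93) and neutrophil-like cells (0.33 against 0.42), and was at 0.43 in B cell-like cells. Collection times are not given in the sources used here, and an effect of the treatment on the clock was not tested.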

How the results depend on the processing

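The settings with pooled macrophage-like and monocyte-like cells, without some clusters, sub-clusters or single cells, and without immunoglobulin genes in the total were chosen after the results were seen, as were the limits on which lists and cell numbers entered. Each library is 1 sample, so counting error is the only error the intervals cover. Of the alternative values for Irf5 in macrophage-like cells, the macrophage-like shares and the engulfment, inflammatory and interferon gamma lists, 67 stayed within their counting interval and 31 moved outside it, and 2 of the 67, both of the engulfment list, turned sign (0.0034 with at least 200 genes per cell, 0.0086 with doublet calls kept). Of the other alternative values, 2938 stayed, 522 moved, and 62 turned sign from a main value outside counting error of 0 or, for a list, outside the range of random lists. From main values inside these, 24 of the 2938 and 4 of the 522 turned sign too, the 4 being in macrophage-like cells: matrix remodelling (-0.045 with cells weighted equally), and with at most 1 foreign marker UMI matrix remodelling (-0.063) and glycolysis (-0.016), and the immediate early list (-0.064 with monocyte-like cells included). Irf5 in macrophage-like cells stayed above 0 in every alternative run. No value was computed with at most 1 foreign marker UMI for T cell-like, neutrophil-like, B cell-like, plasma cell-like, NK cell-like, cDC1-like, ILC2-like and cluster 18 cells because under 100 cells per library were left, or for cluster 18 under other cell filters and clusterings, because clusters are numbered anew there. Of the 36 values of single genes among the 62, the alternative's own counting interval held 0 in 19. Another 18 alternatives gave a gene no ratio, with 0 UMIs in a library and at most 4 in the other. The 62 values that turned sign are given by setting, with the moves of Irf5, the macrophage-like shares and the engulfment, inflammatory and interferon gamma lists, and the cause was not tested.

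At clustering resolution 0.5, the macrophage-like shares were 15.8% (labelled treated) and 12.4% (labelled control). Gzma was at 0.33 in T cell-like cells. The inflammatory list was at -0.27 in macrophage-like cells. Cfd was at or below -2.61, Camp at -0.11 and Ngp at -0.053 in monocyte-like cells. Ccnb1 was at 0.47, Pclaf at 1.29, Ccna2 at 0.90 and the proliferation list at 0.43 in plasma cell-like cells. The regulatory T cell list was at 0.036 in migratory DC-like cells. With macrophage-like and monocyte-like cells together, the joint shares were 36.5% (labelled treated) and 20.2% (labelled control). Irf5 was at 0.27, Saa3 at -0.18, the engulfment list at -0.24, the lysosome list at -0.036, the MHC class II list at -0.029, the T cell activation list at 0.016 and the regulatory T cell list at 0.0012 in these pooled cells. In cells with at most 1 UMI of T cell, B cell and neutrophil markers, Cxcl9 was at -0.17, Saa3 at -1.49, Cd79a at 0.83, the lysosome list at -0.0041, the inflammatory list at -0.23, the interferon gamma list at 0.58, the foam cell list at -0.092 and the type 2 list at 0.054 in macrophage-like cells. Camp was at -0.095, Ngp at -1.02 and the proliferation list at -0.83 in monocyte-like cells. Sgms2 was at -0.030, Prtn3 at 0.56 and the cytotoxic list at -1.61 in migratory DC-like cells. Without the sub-clusters led by other lineages and that of low UMIs, the engulfment list was at -0.10, the inflammatory list at -0.21 and the naive T cell list at 0.031 in macrophage-like cells. With cells weighted equally, the inflammatory list was at -0.21 in macrophage-like cells. The naive T cell list was at 0.013 in monocyte-like cells. The lysosome list was at 0.0095 in ILC2-like cells. With at least 200 genes per cell, the macrophage-like share was 16.7% (labelled treated). The inflammatory list was at -0.20 in macrophage-like cells. Cfd was at -0.19, Camp at -0.27, Ngp at -0.68 and the proliferation list at -0.060 in monocyte-like cells. With at most 10% mitochondrial UMIs, the macrophage-like shares were 16.7% (labelled treated) and 12.8% (labelled control). The inflammatory list was at -0.20 in macrophage-like cells. Cfd was at -0.46, Camp at -0.48 and Ngp at -0.58 in monocyte-like cells. With no mitochondrial maximum, the macrophage-like share was 19.3% (labelled treated). The inflammatory list was at -0.20 in macrophage-like cells. Cfd was at -0.32, Camp at -1.47, Ngp at -0.59 and the proliferation list at -0.53 in monocyte-like cells. At clustering resolution 2, the macrophage-like shares were 21.6% (labelled treated) and 14.9% (labelled control). The inflammatory list was at -0.013 and the interferon gamma list at 0.97 in macrophage-like cells. Cfd was at -3.27, Camp at -1.69, Ngp at -0.72 and the proliferation list at -0.74 in monocyte-like cells. With genes centred within each library, the macrophage-like shares were 16.9% (labelled treated) and 12.9% (labelled control). The inflammatory list was at -0.21 in macrophage-like cells. Cfd was at -3.87 and the proliferation list at -0.25 in monocyte-like cells. The regulatory T cell list was at 0.089 in migratory DC-like cells. With clusters given the same weights in both libraries, the proliferation list was at 0.042 in macrophage-like cells. The proliferation list was at 0.037 in plasma cell-like cells. With doublet calls kept, the macrophage-like shares were 16.1% (labelled treated) and 12.3% (labelled control). The type 17 list was at 0.88 in macrophage-like cells. Ikzf2 was at -0.85 in neutrophil-like cells. Camp was at -0.16, Ngp at -0.0058 and the proliferation list at -0.64 in monocyte-like cells. The engulfment list was at 0.060 in ILC2-like cells. With at least 1000 genes per cell, the macrophage-like share was 20.01% (labelled treated). Mzb1 was at 0.33, Jchain at 1.27 and the cytotoxic list at 0.15 in neutrophil-like cells. Cfd was at -0.40, Camp at -0.46, Ngp at -0.61 and the proliferation list at -0.086 in monocyte-like cells. Without the germinal centre, plasma cell and granulocyte precursor clusters, the macrophage-like shares were 18.9% (labelled treated) and 16.02% (labelled control).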

Other observations

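These observations were chosen after the values were seen, and none is a test. Cdh18, a cadherin gene, was higher in the library labelled treated in 3 lymphocyte classes: UMIs lay in 209 and 24 T cell-like cells, in 92 and 5 B cell-like cells, and in 44 and 0 cells of cluster 18. No cell held more than 10% of its UMIs among T cell-like cells of either library. Slpi, a secreted protease inhibitor, was lower in that library in T cell-like cells (30.7 against 106 CPM), NK cell-like cells (23.3 against 103 CPM) and cluster 18 (24.6 against 134 CPM). Slpi was also among the leading genes of plasma cell-like cluster 15, which held 3.20% and 9.09% of cells.

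Apoe, the apolipoprotein E gene that macrophages commonly express at a high level, had only 83 and 67 UMIs in macrophage-like cells (5.76 and 6.34 CPM, log2 ratio -0.14, -0.62 to 0.35). The level was low in both libraries alike, and the labels name no genotype. In T cell-like cells the list of phagocytosis-restraining and checkpoint signals had a median of 0.55 (0.28 to 0.87 over the alternatives). It joins signals such as Cd47 with the checkpoint genes Cd274 and Pdcd1, and also holds Calr, not itself a restraining signal, and the receptors Sirpa and Pirb. RNA of other cells in these droplets, a source not tested here, may add to it. The median therefore cannot show that T cells held more restraining signals. MHC class II genes had a median of 0.33 there (0.048 with doublet calls kept, 0.90 with genes centred within each library). In plasma cell-like cells the inflammatory list was at 2.05, the engulfment list at 1.67 and the resident macrophage list at 1.63, lists of genes that plasma cells are not known for, and with doublet calls kept these medians were 1.04, 0.88 and 0.92.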
